A study of Mus musculus with 2 samples.

How the data were processed

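Single-cell RNA sequencing was performed on the livers of 2 C57/BL6 mice, one given peanut oil (the Control library) and one given PCB126 at 20 µg/kg/day. PCB126 is a dioxin-like polychlorinated biphenyl that binds the aryl hydrocarbon receptor (AHR). Per the labels' protocols the exposure lasted 5 weeks and was followed by a 12-hour fast. The protocol speaks of a single gavage, whereas the dose is stated per day. The age label gives postnatal day 21, and the sources do not say to which time point that age belongs. The Control mouse carries the treatment label "Untreated" although the protocol gives it the vehicle.

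Per the labels' protocols the livers were dissociated with enzymes, hepatocytes were removed by repeated low-speed spins and a 30 µm strainer, and red cells were lysed. Each sample was then loaded for a target of 6000 cells on a droplet 3′ platform and sequenced on a NovaSeq instrument. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization by the authors. Each comes with a deposited list of genes and a deposited list of barcodes, which hold other content than measured values, namely identifiers in the order of the matrix. Per the file headers the matrices were written by Cell Ranger 6.0.0, while the submitters' processing notes name Cell Ranger 6.1.1 and Seurat 4.0.1. The genome build and annotation are not given in the sources used here. Of the 34244 gene identifiers in the deposited lists, 34132 occur in GENCODE M21 for GRCm38, from which positions were taken. A cell annotation by the authors was not used here, and every cell class was rebuilt from the counts.

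The Control matrix held 8550 barcodes and 24134912 UMIs, and the PCB126 matrix held 4307 barcodes and 16269562 UMIs. A barcode was taken as a cell with at least 500 UMIs, at least 250 detected genes and at most 20% mitochondrial UMIs. This left 1886 of the Control barcodes (22.1%) and 1149 of the PCB126 barcodes (26.7%). In the Control library 6252 barcodes had under 250 genes, against 1460 in the PCB126 library, and a further 412 and 1698 failed on mitochondrial share alone. Scrublet was run in each library, and the barcodes with the highest scores were left out at an expected 0.8% per 1000 barcodes, which removed 28 and 11. Scrublet's own threshold called 8 and 3. The comparisons used 1858 Control cells and 1138 PCB126 cells. The study's filter is not given in the sources used here.

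Counts per 10000 UMIs were log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and 15 neighbours led to Leiden clusters at resolution 1, without integration. Response genes (AHR targets, interferon-stimulated, immediate early, heat shock, mitochondrial, cell cycle, erythrocyte, sex-linked and ribosomal protein genes) were left out of the clustering. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Clusters were named "X-like" from markers of 19 cell types fixed before the data were examined. A marker counted as detected with a log2 fold of at least 1 over the other cells and a UMI in at least 10% of the cluster. The name went to the type with the largest fraction of detected markers, with at least 3 of them. This scoring was chosen after the data were seen, because a mean fold over the markers had given neutrophil clusters a hepatocyte name. Clusters whose top 10 genes held more markers of another type stayed unnamed, as did shallow clusters without an own marker there. The unnamed cells were 41 in the Control library (2.21%) and 91 in the PCB126 library (8.00%).

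With 1 library per group there are no replicates. No test between groups was made, and no p-value or standard error is given. Raw UMIs were summed per library and class and scaled by the class total (CPM). Ratios are PCB126 over Control unless stated otherwise. Intervals are exact 95% intervals (Clopper-Pearson for a share, Poisson for a count, conditional binomial for a ratio), and they and the limits allowed by 3 counts cover counting error only. A fold against a sum of 0 was computed against 3 counts in the class. For log2 ratios 0.5 counts were added to each sum. Classes with at least 100 cells in each library entered the planned comparisons. Classes with at least 50 cells in each library (cholangiocyte-like and dendritic-like) were added after the data were seen. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, and without thinning.

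For each of 41 gene lists fixed before the data were examined, the median log2 ratio over members with at least 20 UMIs in the class was taken where at least 4 such members existed. Its percentile came from 10000 random lists of the same size matched on expression. Named genes were chosen by a rule fixed at the same time. Genes were ranked by the bound of the ratio's interval nearest to 1, among genes with at least 100 UMIs in the class of the higher library and at least 25% of their highest CPM in any class of that library with at least 100 cells. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed gene models and markers of other classes were left out. The first 8 genes on each side were taken in the planned classes and the first 3 in the added classes, of which 1 gene is not reported here. Any member of a reported list could also be named. Which lists and list members to report, and which values count as main results, was decided after the values were seen.

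The ratio and list steps were tested on simulated data. With 2 simulated libraries of the size of a large class (10995 genes), the interval of a gene changed 2-fold lay on the right side of 1 for 84.9% of genes and that of a gene changed 4-fold for 98.0%. For a small class (6871 genes) the values were 78.9% and 95.6%. The interval covered 1 for 96.2% of unchanged genes in both. The simulation holds counting error alone and no variation between cells or between mice.

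Settings varied by plan were a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, clustering each library alone, and clustering with the response genes kept. Also varied by plan were other denominators for shares, ratios centred on the median gene, the mean over cells and thinning. Further planned settings were subtraction of an ambient profile, a minimum of 100 UMIs for list members, and 2 counts added. The ambient profile was the sum of all barcodes of a library, cells included. Its amount in a class was set by the hepatocyte genes, at 41.3% of the UMIs in Control and 16.6% in PCB126 neutrophil-like cells. A gene rarer in a class than in the library can thus fall to 0, so this setting does not measure free RNA. Chosen after seeing the data were 2 settings with barcodes up to 50% mitochondrial UMIs. The same holds for clusters with at least 15 cells in each library weighed equally. It also holds for class totals without the mitochondrial genes, Gm42418, AY036118 and Lars2.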

Results

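The study asked how non-parenchymal cells of the mouse liver respond to PCB126. The data were 2 single-cell libraries, 1 from a vehicle mouse (Control) and 1 from a mouse given PCB126, so there were no replicates and mouse and treatment could not be told apart. All ratios compare these 2 libraries. Their intervals cover counting error only. Of 157 gene ratios computed again under other settings, 117 moved by more than 1.5 times in at least 1 of them, and 38 of the 141 above 1.5 times came under it or changed sides. The 1858 Control cells held 13754218 UMIs, with a median of 5258 UMIs and 1473 genes per cell. The 1138 PCB126 cells held 9871419 UMIs, with medians of 6567 UMIs and 2150 genes. After thinning to 1000 UMIs the median genes per cell were 477 and 534. The median mitochondrial share was 7.58% in the Control cells and 12.3% in the PCB126 cells. The non-coding transcript Gm42418, which overlaps ribosomal RNA, took 8.39% and 9.51% of the UMIs, and 21.1% and 14.5% in the LSEC-like cells defined below.

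Leukocyte-like cells made up most of the Control cells (74.8%). Endothelial-like cells were the largest group of the PCB126 cells (51.85%, 95% interval 48.9 to 54.8). Neutrophil-like cells were 758 of 1858 Control cells (40.8%, 95% interval 38.6 to 43.1) and 100 of 1138 PCB126 cells (8.79%, 7.21 to 10.6). Monocyte-like cells were 477 (25.7%, 23.7 to 27.7) and 11 (0.967%, 0.484 to 1.72). Cells like liver sinusoidal endothelial cells (LSEC-like), the fenestrated lining of the sinusoids, were 143 (7.70%, 6.53 to 9.0) in the Control library and 459 (40.3%, 37.5 to 43.3) in the PCB126 library. The LSEC-like share was 5.24 times higher in the PCB126 library (4.34 to 6.37), the neutrophil-like share 4.64 times higher in the Control library (3.77 to 5.78), and the monocyte-like share 26.6 times higher in the Control library (14.7 to 53.6). The monocyte-like ratio does not compare like cells. All 11 PCB126 cells lay in cluster 7, which was led by granule genes, and they stood apart from the 477 Control cells in Lyz2 (575 against 4870 CPM) and Cd74 (7586 against 474.1 CPM).

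Vascular endothelial-like cells were 127 (6.84%) and 131 (11.5%), a ratio of 1.68 (1.31 to 2.17). Dendritic-like cells were 58 (3.12%) and 128 (11.2%), cholangiocyte-like cells of the bile ducts 71 (3.82%) and 86 (7.56%), T-like cells 18 (0.969%) and 70 (6.15%), and B-like cells 20 (1.08%) and 55 (4.83%). Plasma-like cells were 58 (3.12%) and 6 (0.527%), and erythroid-like cells 87 (4.68%) and 1 (0.0879%). Without doublet removal the erythroid-like cells were 126 (6.68%) and 32 (2.785%), a rise larger than the 28 and 11 barcodes kept. Unnamed cells were then 6 and 44, against 41 and 91, so other cells changed class in that clustering. No cluster carried the names Kupffer-like, stellate-like or hepatocyte-like, but other settings named some. With each library clustered alone 70 Control cells (3.77%) were Kupffer-like, and with barcodes up to 50% mitochondrial UMIs clustered again 123 Control cells (5.55%) and 23 PCB126 cells (0.991%) were hepatocyte-like. Among unnamed cells was a cluster with the complement and macrophage genes C1qa, C1qb, C1qc, Gpnmb and Trem2 among its top 10, with 6 Control cells (0.323%) and 44 PCB126 cells (3.87%). The other unnamed cluster was shallow, with 35 and 47 cells, and its best match was LSEC (13 of 15 markers).

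**Figure D1:**
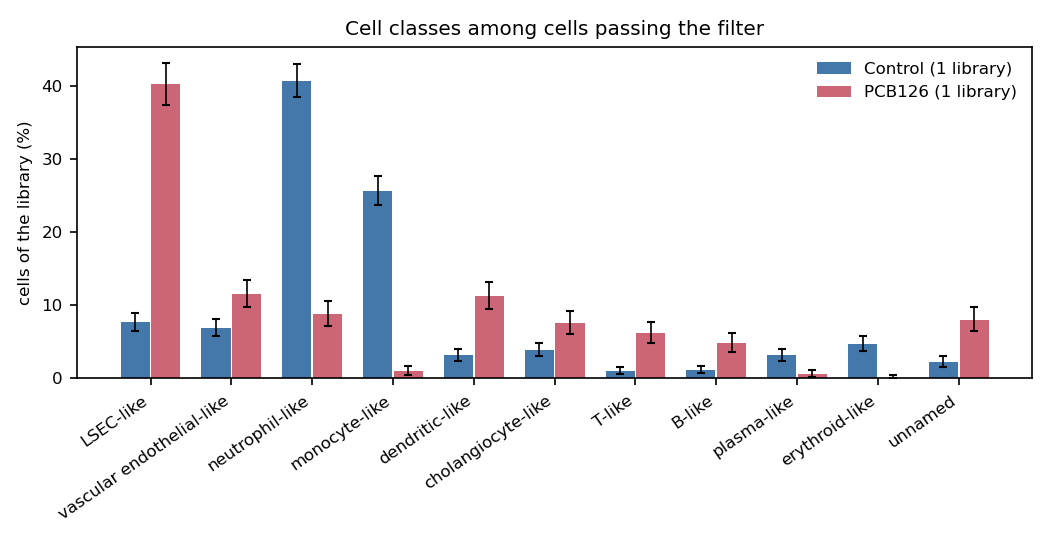
Share of cells (%) of each class among cells passing the filter, 1 library per group, with exact 95% intervals that cover counting error only. Neutrophil-like and monocyte-like bars are taller in the Control library (40.8% and 25.7%), and the LSEC-like bar is taller in the PCB126 library (40.3%).

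These shares describe the suspensions after hepatocyte removal, red cell lysis and the filter, not the livers. The filter left out 1698 PCB126 barcodes and 412 Control barcodes on mitochondrial share alone. With barcodes up to 50% mitochondrial UMIs added, the vascular endothelial-like share ratio was 1.04 when they were matched to the clusters and 0.928 when all were clustered again. Clustered again, the LSEC-like share ratio was 17.1. Of the PCB126 cells 32.4% were then LSEC-like, 4.40% vascular endothelial-like and 37.5% unnamed. At most 10% mitochondrial UMIs, 13.55% of the PCB126 cells were LSEC-like, none vascular endothelial-like and 39.4% unnamed.

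Different clusters held several of these classes in the 2 libraries. Of the LSEC-like cells, cluster 3 held 112 Control and 15 PCB126 cells, cluster 6 held 24 and 176, and cluster 15 held 7 and 268. Of the neutrophil-like cells, cluster 8 held 421 and 24, cluster 9 held 284 and 6, cluster 18 held 25 and 67, and cluster 20 held 28 and 3. The monocyte-like cells were cluster 0, with Ear2, Cd300e and Treml4 among its top 10 genes and 417 Control and 0 PCB126 cells, and cluster 7, led by the granule genes Prtn3, Mpo and Elane, with 60 and 11. Neutrophil-like cluster 8 had the inflammatory genes Il23a, Tnf and Ptgs2 among its top 10. The vascular endothelial-like clusters were shared almost evenly, with 89 and 91 cells in cluster 5 and 38 and 40 in cluster 11. A cluster filled mostly by 1 library cannot be told from an effect of that library.

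The AHR response was asked of each class through Cyp1a1, the monooxygenase gene most widely used as a readout of AHR activation. Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824, GRCm38) was 280 times higher in the LSEC-like cells of the PCB126 library (167 to 513), a log2 ratio of 8.08 that ranged from 5.20 to 11.44 over the alternatives. It stood at 17.3 CPM (14 UMIs) in the Control library and 4847 CPM (13364 UMIs) in the PCB126 library. In the vascular endothelial-like cells Cyp1a1 was 288.9 CPM in the Control library and 5422 CPM in the PCB126 library, a ratio of 18.8 (16.9 to 20.9). In neutrophil-like cells of the PCB126 library Cyp1a1 stood at 27.5 CPM, in dendritic-like cells at 4.78 CPM and in cholangiocyte-like cells at 73.1 CPM.

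After thinning, Cyp1a1 was seen in 1 of 143 LSEC-like cells of the Control library (0.699%) and in 426 of 459 of the PCB126 library (92.8%, 90.0 to 95). In vascular endothelial-like cells it was seen in 24 of 127 (18.9%, 12.5 to 26.8) and in 122 of 131 (93.1%, 87.4 to 96.8). Unthinned, the shares with a Cyp1a1 UMI were 2.80% and 99.1% in LSEC-like cells and 55.9% and 99.2% in vascular endothelial-like cells. Thinning left out 16 Control and 4 PCB126 cells over all classes and none of these endothelial-like cells. As background, Cyp1a1 was seen after thinning in 0 of 128 dendritic-like cells of the PCB126 library (5.47% unthinned, median 14626 UMIs) and in 0 of 100 neutrophil-like cells (10.0% unthinned, median 3948 UMIs), and in 2 of 70 T-like cells (2.86%, and 21.4% unthinned, median 6796 UMIs). The median depths of the LSEC-like and vascular endothelial-like cells of that library were 5683 and 8960 UMIs.

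**Figure D2:**
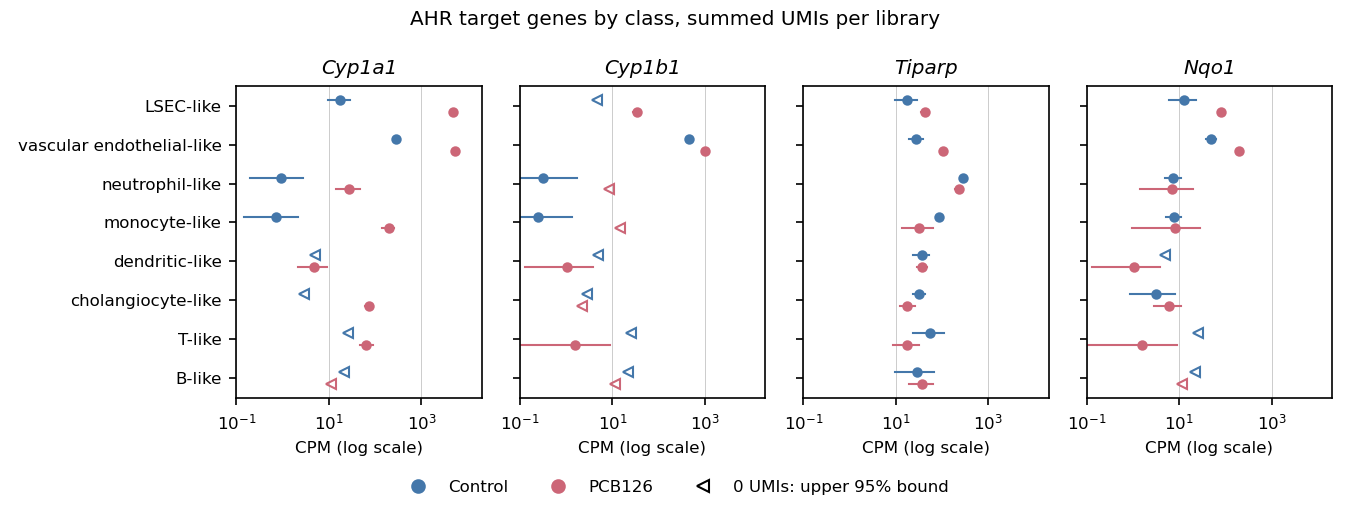
CPM (log scale) of 4 AHR target genes by class and library, with exact 95% intervals; open triangles mark the upper bound where no UMI was counted. Cyp1a1 reaches 4847 CPM in LSEC-like and 5422 CPM in vascular endothelial-like cells of the PCB126 library.

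In the LSEC-like cells the PCB126 library carried higher AHR target, antioxidant, metallothionein and iron storage, and MHC class I transcripts. Most members of the mixed inflammatory cytokine and NF-kB list were lower. All 5 measured members of the AHR gene battery were above 0, with a median log2 ratio of 2.62 (percentile 100 among random lists), which was 1.24 after thinning and 4.94 with the ambient profile subtracted. Cyp1b1, another AHR-regulated monooxygenase, had 0 UMIs in the Control library and 96 in the PCB126 library, at least 9.39-fold higher. Those UMIs lay in 16 of 459 cells (3.49%). With the response genes kept in the clustering, 18 Cyp1b1 UMIs over both libraries were left in the LSEC-like class. The PCB126 library then held 454 LSEC-like and 142 vascular endothelial-like cells, against 459 and 131. Most of the Cyp1b1 signal thus depended on a few cells that changed class. Whether the 16 cells were vascular endothelial cells was not tested. Nqo1, a quinone reductase, was 6.46 times higher (3.44 to 13.7), and Tiparp, an AHR-induced repressor of the receptor, had log2 1.27 (0.42 at most 10% mitochondrial UMIs). Xdh had log2 0.10. Ahr itself was 2.46 times higher (1.81 to 3.42; log2 1.29, and 0.47 with barcodes up to 50% mitochondrial UMIs clustered again), and the 5 members of the AHR complex had a median of 0.26.

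Of the 14 measured NRF2 and antioxidant genes, 13 were above 0 in LSEC-like cells (median 0.80, percentile 100). Txnrd1, thioredoxin reductase, was 3.52 times higher (2.41 to 5.34), Osgin1 3.85 times (1.96 to 8.62; log2 1.87, ranging from 0.30 to 5.61 over the alternatives) and Nfe2l2, which encodes NRF2, 2.06 times (1.73 to 2.48). Gpx1 was below 0 (log2 -0.31) and Hmox1 had log2 0.14. All 5 metallothionein and iron storage genes were above 0 (median 1.19), with Ftl1, ferritin light chain, 3.39 times higher (3.08 to 3.73) and Mt1 2.98 times (2.59 to 3.43). Nuclear genes of oxidative phosphorylation were above 0 in 13 of 14 cases (median 0.64), with Cox7a2 3.05 times higher. Heat shock genes were above 0 in 8 of 9 (median 0.55). The mitochondrially encoded genes had a median of 0.28. With the mitochondrial genes, Gm42418, AY036118 and Lars2 left out of the class total, the medians were 0.71 (antioxidant), 1.09 (metallothionein and iron storage), 0.54 (oxidative phosphorylation) and 0.45 (heat shock). Over all alternatives they ranged, in the same order, from 0.30 to 1.74, 0.64 to 1.58, 0.12 to 1.28 and 0.15 to 0.97. The lowest oxidative phosphorylation and heat shock values lay near the median over all genes with at least 100 UMIs (0.105 in the main setting).

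All 10 MHC class I presentation genes were above 0 in LSEC-like cells (median 0.91, percentile 100). H2-D1, a classical class I heavy chain, was 2.09 times higher (1.92 to 2.28), H2-Q7 2.83 times (2.19 to 3.71) and the immunoproteasome subunit Psmb9 3.15 times (2.03 to 5.12), while Tapbp had log2 0.00. The interferon-stimulated list had a median of 0.16, with 10 of 14 members above 0, and fell below 0 in 2 of 17 alternatives. Of 8 inflammatory cytokine and NF-kB genes, 7 were below 0 (median -1.28, percentile 0). That median was -0.58 with the ambient profile subtracted, -0.53 at most 10% mitochondrial UMIs and -0.51 after thinning, and neutrophil granule genes had a median of -3.23 in the same cells. Icam1, a leukocyte adhesion molecule, stood at 132.2 CPM in the Control library and 52.2 CPM in the PCB126 library, 2.53 times higher in the Control library (1.95 to 3.27). Vcam1 was 2.31 times higher in the Control library (1.83 to 2.91; log2 -1.21, and -0.38 with clusters weighed equally), and Nfkbia had log2 0.06.

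The LSEC identity list was divided, with 6 members above and 6 below 0 (median -0.05). Clec4g was 1.42 times higher in the PCB126 library (1.32 to 1.53), and Stab2, a scavenger receptor, stood at 820.5 CPM in the Control library and 748 CPM in the PCB126 library (log2 -0.13, above 0 when thinned and at Leiden resolution 0.5). Of 7 capillarization genes 6 were below 0 (median -0.20), with Vwf at 87.7 and 11.2 CPM. Of 14 angiocrine genes 10 were above 0 (median 0.31), among them the flow-responsive factor Klf2 at 2.26 times (1.92 to 2.67), while endothelin gene Edn1 was 6.0 times higher in the Control library (4.19 to 8.66). Immediate early genes had a median of 0.08, which ranged from -0.44 to 5.33 over the alternatives, with 10 of 17 above 0.

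Zonal endothelial genes differed in the class sums, but their medians lay near 0 or on the other side of 0 within clusters 3 and 6. Of 8 pericentral genes 7 were above 0 (median 0.95), with Wnt9b 4.79 times (2.74 to 9.14), Lhx6 3.25 times and Kit 2.32 times higher. Of 8 periportal genes 7 were below 0 (median -0.75), with Ntn4 2.98 times and Msr1 2.96 times higher in the Control library. Within clusters 3 and 6, each weighed equally, the pericentral median was 0.06 and the periportal median 0.26, with Ntn4 (0.22) and Msr1 (0.46) above 0. This setting left out cluster 15, which held 268 of the 459 PCB126 cells, and cluster 3 held 15 PCB126 cells. Msr1 was also above 0 (0.74) with barcodes up to 50% mitochondrial UMIs clustered again. Wnt9b (2.21) was at 0.40 after thinning, and Kit (1.21) at 0.46 within the clusters.

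Among the 16 genes named by size in LSEC-like cells, Cyp1a1 and Nqo1 stood with Hpgd, which encodes the prostaglandin-degrading enzyme, at 4.37 times (3.38 to 5.75), Ada, adenosine deaminase, at 8.62 times (4.30 to 20.2) and the chemokine scavenger Ackr3 at 7.09 times (3.37 to 17.9). Higher in the Control library were the matricellular gene Ctgf at 4.28 times (3.87 to 4.73) and the glucosylceramide synthase gene Ugcg at 3.59 times (2.89 to 4.47). Of the 16 genes, 10 were also among the top 10 genes of LSEC-like clusters, which the 2 libraries filled unequally. They were Cyp1a1, Ltc4s, Slc18a2 and Cyp26b1 for cluster 6 and Esm1, Abcc9, Armcx4, Clca3a1, Galnt15 and Cd36 for cluster 3, and of these Cyp1a1 was left out of the clustering. Within the matched clusters all 16 kept their direction, with Cyp1a1 at log2 6.60, Ltc4s at 3.27 (3.63 in the class), Slc18a2 at 2.87 (3.49), Cyp26b1 at 1.80 (2.00), Cd36 at -0.90 (-1.71) and Esm1 at -0.36 (-4.16). Nqo1 was at 1.27 (2.62), Ackr3 at 1.55 (2.73), Hpgd at 1.44 (2.12), Ctgf at -1.34 (-2.10) and Ugcg at -1.02 (-1.84).

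Transcripts of other cells were lower in the LSEC-like cells of the PCB126 library. All 5 erythrocyte genes were below 0 (median -2.84), all 4 neutrophil granule genes were below 0 (median -3.23), and 10 of 12 hepatocyte genes were below 0 (median -1.51). The median log2 ratio over all genes with at least 100 UMIs was 0.105 in this class, and centring on it left every list median named for LSEC-like cells on its side of 0, except that of the immediate early genes (-0.03).

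**Figure D3:**
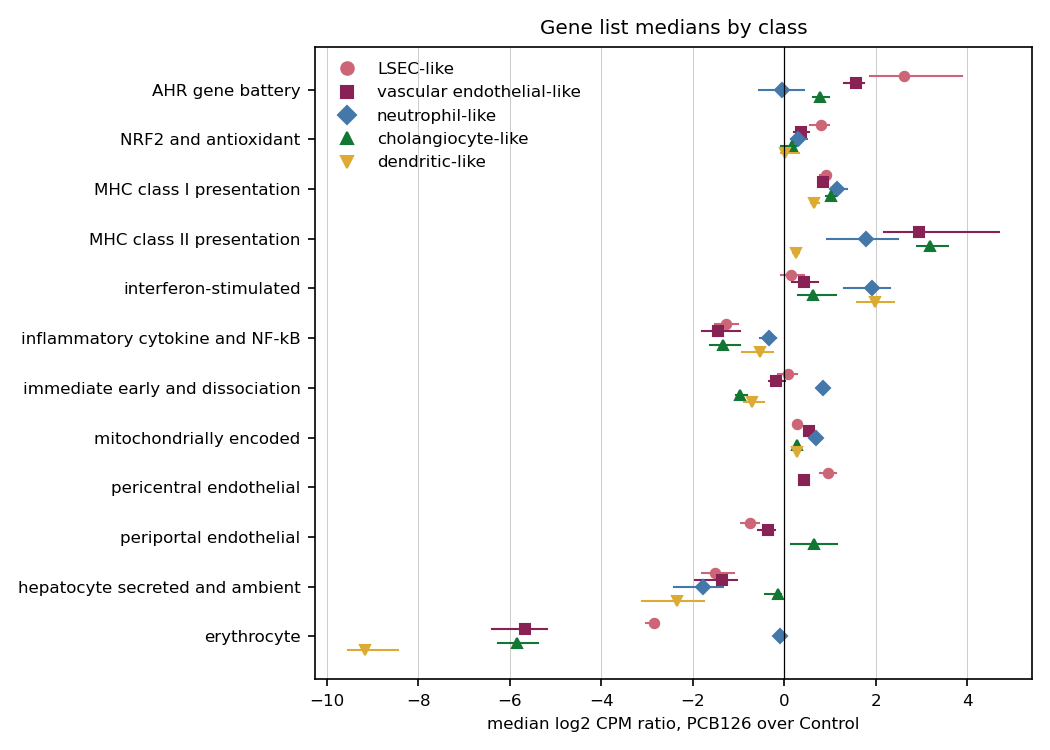
Median log2 CPM ratio, PCB126 over Control, of gene lists in 5 classes, with intervals from redrawing the counts. The AHR gene battery lies at 2.62 in LSEC-like and 1.57 in vascular endothelial-like cells, and the MHC class I list lies above 0 in all 5 classes.

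Vascular endothelial-like cells, the lining of larger liver vessels, carried more AHR target and MHC class I transcripts and fewer inflammatory transcripts in the PCB126 library. All 6 measured AHR battery genes were above 0 (median 1.57, percentile 100). Cyp1b1 stood at 447 CPM in the Control library and 1024 CPM in the PCB126 library. Its log2 ratio of 1.195 ranged from 1.10 to 8.98 over the alternatives. Tiparp was 3.87 times higher (2.67 to 5.74) and Nqo1 4.05 times (3.07 to 5.40). Of 14 NRF2 and antioxidant genes 12 were above 0 (median 0.37), with Gclc, of glutathione synthesis, 2.20 times higher (1.61 to 3.04), but the median was -0.04 after thinning. Of 10 MHC class I genes 9 were above 0 (median 0.84), with H2-Q7 3.28 times (2.74 to 3.94) and H2-D1 1.78 times higher (1.66 to 1.90).

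All 7 measured inflammatory genes were below 0 in vascular endothelial-like cells (median -1.44, percentile 0). Vcam1 was 2.83 times higher in the Control library (2.40 to 3.36), Icam1 2.00 times (1.64 to 2.44) and the chemokine gene Cxcl10 9.24 times (3.35 to 35.5, with 41 and 4 UMIs). Of 14 interferon-stimulated genes 12 were above 0 (median 0.43), with Ifit3 2.52 times higher (1.56 to 4.16; log2 1.32). When each library was clustered alone the median was -0.38 and Ifit3 was at 0.041. Capillarization genes were below 0 in 6 of 7 (median -0.59), with the coagulation gene Vwf 1.94 times higher in the Control library (1.81 to 2.08; log2 -0.95, and -0.55 with barcodes up to 50% mitochondrial UMIs clustered again). The LSEC identity list had 9 of 11 members below 0 (median -0.47, but 0.18 when each library was clustered alone). The pericentral list had 6 of 8 above 0 (median 0.43, ranging from 0.36 to 5.20 over the alternatives). The periportal list had 5 of 7 below 0 (median -0.34, ranging from -2.03 to -0.27). Immediate early genes had a median of -0.17. The 4 measured MHC class II genes were above 0 (median 2.94) at low levels, with Cd74 at 7 and 31 UMIs and H2-Aa at 0 and 29 UMIs. Subtracting the ambient profile left 0 UMIs of both genes and 0 members of the list. As that profile holds the cells too, the subtraction cannot tell free RNA from low expression. The list median was thus not told apart from background.

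The 16 genes named by size in vascular endothelial-like cells included, on the PCB126 side, Cyp1a1, Nqo1, Tiparp, H2-Q7, Hpgd at 4.21 times (3.14 to 5.72), Arl4d at 3.74 times (2.77 to 5.14), Timp3, a metalloproteinase inhibitor, at 2.67 times (2.51 to 2.84; log2 1.42, but 0.96 within clusters and 0.41 with each library clustered alone) and the tight junction gene Cldn5 at 3.06 times (2.42 to 3.89). On the Control side Ackr1, the chemokine-binding receptor of venules, was 24.9 times higher (12.9 to 55.2), Bmp4 3.61 times (3.08 to 4.24), Lrg1 3.44 times (2.99 to 3.97) and Cd55, a complement regulator, 3.16 times (2.85 to 3.50). The contractile genes Acta2, Myh11, Myl9 and Tpm2 were also named on the Control side, with Acta2 at 283.7 and 37.3 CPM. UMIs of 5 contractile and mural genes lay in few cells. All 1156 such UMIs of the Control library were in its top 5 cells, 2 of which had at least 20, and all 193 of the PCB126 library in its top 5 cells, 1 of which had at least 20. The stellate activation and matrix list, with Acta2 and Tagln in it, had 5 of 6 members below 0 (median -1.33). With each library clustered alone the class held 28 Control and 148 PCB126 cells, and Acta2, Myh11, Myl9, Tpm2, Tagln, Bmp4, Cldn5, Isg15 and Stab1 had the opposite direction.

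Beside these lists, all 4 erythrocyte genes (median -5.66), all 6 hepatocyte genes (median -1.35) and all 4 neutrophil granule genes (median -2.98) were below 0 in vascular endothelial-like cells, and the mitochondrially encoded genes had a median of 0.55.

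**Figure D4:**
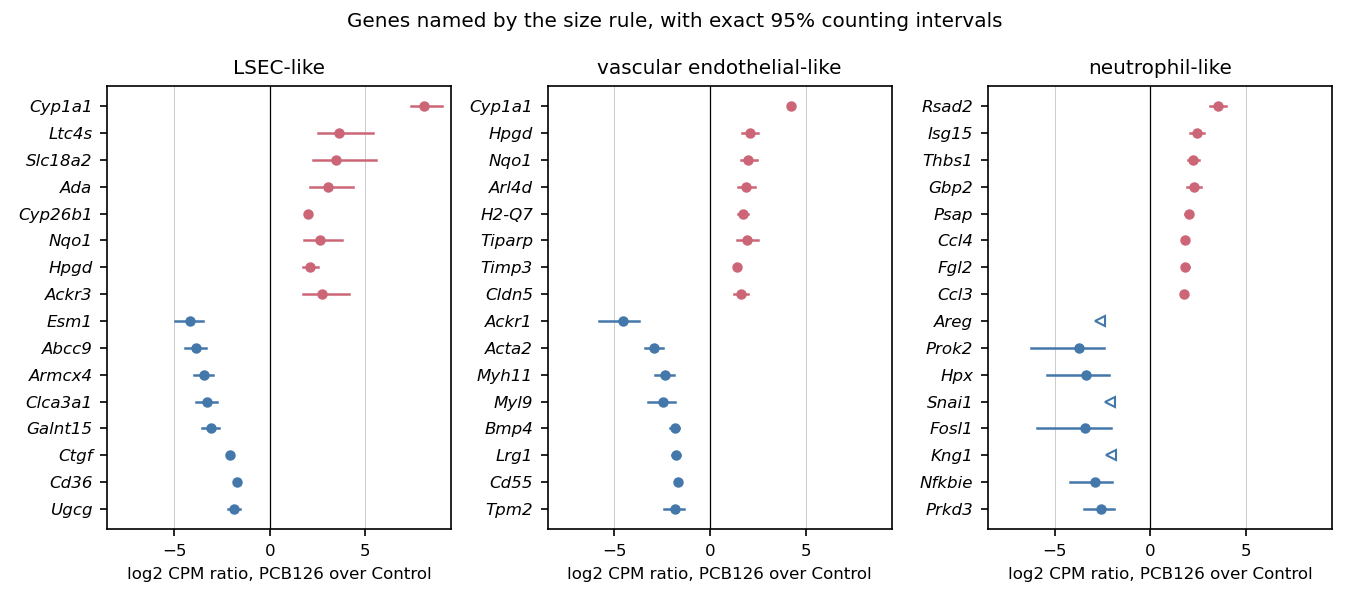
Log2 CPM ratio, PCB126 over Control, of the genes named by the size rule in 3 classes, with exact 95% counting intervals; open triangles mark bounds against a sum of 0. Cyp1a1 has the highest ratio in LSEC-like (8.08) and vascular endothelial-like cells (4.23), and Rsad2 in neutrophil-like cells (3.54).

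Neutrophil-like cells of the PCB126 library carried more interferon-stimulated, MHC class I and immediate early transcripts. The median of the measured AHR battery genes, without Cyp1a1, lay near 0. Of 11 interferon-stimulated genes 10 were above 0 (median 1.93, percentile 100). Rsad2, the antiviral protein viperin, was 11.7 times higher (8.76 to 15.6), Isg15 5.38 times (4.16 to 6.93) and Ifit1 11.6 times (5.65 to 24.4). All 10 MHC class I genes were above 0 (median 1.17), with the peptide transporter Tap1 4.82 times higher (3.39 to 6.81) and H2-Q7 16 times (9.57 to 27.4). The 4 measured AHR battery genes had a median of -0.05, with 2 members on each side, and Tiparp stood at 279.9 and 236 CPM. The median was above 0 in 3 of 13 alternatives.

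Immediate early genes, which also respond to tissue dissociation, were above 0 in 13 of 14 cases (median 0.85), with Fos 2.73 times higher (2.63 to 2.83) and Jun 2.36 times (2.27 to 2.46), while Nr4a1 was 1.89 times higher in the Control library (1.70 to 2.10). The inflammatory list was divided, with 5 members above and 9 below 0 (median -0.33). The chemokine genes Ccl4 and Ccl3 were 3.46 times (3.21 to 3.73) and 3.34 times higher (3.09 to 3.62), or log2 1.79 and 1.74. These were 2.78 and 2.80 within clusters 8 and 18 weighed equally, and 1.00 and 0.14 at most 10% mitochondrial UMIs. Cxcl2 was 1.48 times (1.45 to 1.52) and Nfkbia 1.85 times higher in the Control library (1.75 to 1.96). The neutrophil granule list had a median of -0.11, which was above 0 in 3 alternatives, with S100a8 and S100a9 1.89 and 1.83 times higher in the Control library (log2 -0.92 and -0.87, but -0.30 and -0.35 at most 10% mitochondrial UMIs). Heat shock genes had a median of 0.74, with 6 of 8 above 0, and -0.11 at most 10% mitochondrial UMIs. Of 9 cholesterol synthesis genes 8 were below 0 (median -1.65, or -0.996 with sums of 0 at their bound), with Hmgcs1 at 89 and 0 UMIs, at least 4.03-fold lower in the PCB126 library. Within clusters 8 and 18 weighed equally that median was 0.85.

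Further genes named by size on the PCB126 side in neutrophil-like cells were Thbs1 at 4.76 times (3.94 to 5.76), the guanylate-binding protein gene Gbp2 at 4.87 times (3.80 to 6.23), Psap at 4.01 times (3.50 to 4.58) and Fgl2 at 3.56 times (3.12 to 4.05). Within clusters 8 and 18 weighed equally, log2 was 4.91 for Thbs1 (2.25 in the class), 3.44 for Gbp2 (2.29), 2.87 for Psap (2.00) and 1.13 for Fgl2 (1.83), and Thbs1 ranged from 0.59 to 4.91 over the alternatives. On the Control side, Areg, a ligand of the epidermal growth factor receptor, had 169 and 0 UMIs, at least 7.66-fold lower in the PCB126 library, and Snai1 and Kng1 had 121 and 115 UMIs against 0, at least 5.49-fold and 5.21-fold lower. Prok2, among the top 10 genes of cluster 9, was 15.6 times higher in the Control library (5.29 to 76.0; log2 -3.74, but -0.44 within those clusters), Fosl1 12.4 times (4.19 to 60.4; log2 -3.41, and -2.15 within those clusters), Nfkbie 7.99 times (4.02 to 18.6) and Prkd3 6.22 times (3.74 to 11.2). The plasma protein genes Hpx and Kng1 are expressed by hepatocytes, and Hpx was 11.5 times higher in the Control library (4.46 to 42.5). The 14 hepatocyte genes were all below 0 (median -1.78), as were the 9 acute phase genes (median -1.47, with Saa3 at 628 and 5 UMIs), while the erythrocyte genes had a median of -0.10 and the mitochondrially encoded genes one of 0.71. Of the erythrocyte genes, Hbb-bs (log2 -0.04) ranged from -6.79 to 12.29 over the alternatives.

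Cholangiocyte-like cells, a single cluster, carried more MHC class II and class I transcripts and fewer immediate early and inflammatory transcripts in the PCB126 library. All 6 measured MHC class II genes were above 0 (median 3.20, percentile 100). Cd74, the invariant chain, stood at 73.4 and 700 CPM, a ratio of 9.53 (7.72 to 11.9), and H2-Aa at 4.69 and 164 CPM, a ratio of 35 (15.9 to 96.2). All 10 MHC class I genes were above 0 (median 1.03), and 11 of 13 interferon-stimulated genes were above 0 (median 0.63). Igtp, an interferon-inducible GTPase gene, was 4.39 times higher (2.88 to 6.94) and H2-Q7 2.83 times (2.39 to 3.36). The AHR battery had 4 of 5 members above 0 (median 0.77), among them Cyp1a1 with 0 and 123 UMIs and Cyp1a2 with 2 and 56 UMIs, a ratio of 21.3 (5.63 to 180.3). The 56 UMIs lay in 9 of 86 cells (10.5%), and Tiparp, with 41 and 30 UMIs, was below 0 (log2 -0.84). Hepatocyte genes together made up 9880 and 7937 CPM in cholangiocyte-like cells, against 496.7 and 212.5 CPM in LSEC-like cells. Whether hepatocyte RNA or mixed droplets brought the Cyp1a2 UMIs was not tested.

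All 14 immediate early genes were below 0 in cholangiocyte-like cells (median -0.97), with Atf3 5.61 times (4.80 to 6.59), Egr1 2.90 times and Fos 2.45 times higher in the Control library. Of 7 inflammatory genes 6 were below 0 (median -1.33), with the neutrophil chemokine gene Cxcl1 4.30 times higher in the Control library (2.74 to 6.95). The neutrophil genes S100a8 and S100a9 together stood at 74.2 and 3.57 CPM in the same cells. Whether neutrophil RNA contributed to the inflammatory counts was not tested. Hes1, a Notch target, was 3.26 times (3.06 to 3.47) and Hamp, which encodes hepcidin, 25.1 times higher in the Control library (14.4 to 47.7). Hamp is a hepatocyte gene, and the 5 acute phase genes were below 0 (median -0.97). The hepatocyte list had a median of -0.13 and the erythrocyte list one of -5.84, and Hbb-bs stood at 2023 and 13.7 CPM.

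Dendritic-like cells of the PCB126 library carried more interferon-stimulated transcripts. Of 16 such genes 15 were above 0 (median 1.98, percentile 100), with Isg15 7.47 times higher (4.77 to 12.4) and Ifi204 8.81 times (4.18 to 22.3). Over the alternatives the median ranged from 1.04 to 2.48. The log2 ratio of Isg15 (2.87) ranged from 1.37 to 4.53 and that of Ifi204 (3.045) from 1.31 to 3.95. Gbp2 and Iigp1, both interferon-inducible GTPase genes, had 0 Control UMIs against 286 and 182, at least 37.5-fold and 23.8-fold higher. The chemokine gene Ccl17 had 1 and 652 UMIs, a ratio of 256 (45.8 to 10136), and was among the top 10 genes of cluster 16, which held 25 Control and 76 PCB126 cells. Within clusters 1 and 16 weighed equally its log2 ratio was 6.79. MHC class I genes were above 0 in 10 of 10 (median 0.65) and MHC class II genes in 7 of 8 (median 0.25), with Cd74 at 13569 and 17442 CPM.

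Immediate early genes were below 0 in 12 of 14 cases (median -0.70) and inflammatory genes in 7 of 10 (median -0.52) in dendritic-like cells. Il1b was 8.30 times (5.93 to 11.8), Ccl4 6.01 times (4.78 to 7.60), Ifitm2 3.50 times (3.07 to 3.99) and Naaa, among the top 10 genes of cluster 1, 3.38 times higher in the Control library (3.04 to 3.76). All 11 cholesterol synthesis genes were below 0 (median -0.83), as were all 7 erythrocyte genes (median -9.16). Neutrophil granule genes (median -2.81) and hepatocyte genes (median -2.34) were lower too. With the ambient profile subtracted the inflammatory median was 0.14 and 9 UMIs of Il1b were left, too few for a ratio. With each library clustered alone the immediate early median was 0.42, the inflammatory median 0.78 and the log2 ratio of Ccl4 2.19.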

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

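The test of dendritic-like RNA as the origin of MHC class II counts was written down before its result was seen, and the other tests weighed here were chosen only after the results they bear on.

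Barcodes left out of the comparisons carried a signal. Among barcodes with at least 250 genes and over 20% mitochondrial UMIs, Cyp1a1 stood at 2210 CPM in the PCB126 library (1698 barcodes, interval 2165 to 2255) and at 9.87 CPM in the Control library (412 barcodes). LSEC markers together made up 13291 CPM in these PCB126 barcodes.

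Among lists with medians on both sides of 0, 4 drew attention because the median lay in the upper 2.5% of random lists in 1 class and in the lower 2.5% in another, with counting intervals clear of 0; none of these differences was tested, as there was 1 library per group. The LSEC identity list was higher in the PCB126 library in cholangiocyte-like cells (1.55) and lower in vascular endothelial-like cells (-0.47), a difference of 2.03. The first of these rests on 4 genes, Maf, F8, Mrc1 and Gpr182, with 303, 33, 19 and 15 UMIs in the PCB126 library, and free endothelial RNA was not excluded as their origin. The second was 0.18 with each library clustered alone, which ends the contrast. Immediate early genes were higher in neutrophil-like cells (0.85) and lower in cholangiocyte-like cells (-0.97), a difference of 1.81. Metallothionein and iron storage genes were higher in LSEC-like cells (1.19) and lower in cholangiocyte-like cells (-0.65), a difference of 1.84. Periportal endothelial genes were higher in cholangiocyte-like cells (0.65) and lower in LSEC-like cells (-0.75), a difference of 1.40. The LSEC-like median was 0.26 with clusters weighed equally and 0.24 with barcodes up to 50% mitochondrial UMIs clustered again, so this contrast ended there too.

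The Control library held more neutrophil-like and monocyte-like cells and the PCB126 library more LSEC-like cells. The mitochondrial filter alone is argued against, since with barcodes up to 50% mitochondrial UMIs matched to the clusters the LSEC-like share was still 5.10 times higher in the PCB126 library (4.37 to 5.98). More blood in the Control suspension may contribute, as barcodes led by hemoglobin were 31.4% of the Control barcodes and 3.25% of the PCB126 barcodes. For T-like and B-like cells per LSEC-like cell the ratio Control over PCB126 was 0.976, with an interval on both sides of 1 (0.635 to 1.46), whereas neutrophil-like cells per LSEC-like cell were 5.30 and 0.218. The makeup of that blood is not known, so blood, dissociation, a difference between the mice and an effect of PCB126 cannot be told apart.

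Cyp1a1 UMIs were also found outside endothelial-like cells in the PCB126 library, where RNA freed from endothelial cells might place them. In T-like cells Cyp1a1 stood to the summed LSEC markers as in endothelial-like cells (relative ratio 0.839, 0.576 to 1.13). Free RNA predicts this only if it keeps the proportion of cells passing the filter, with 19913 Cyp1a1 and 90467 marker UMIs. In PCB126 barcodes with under 250 genes and over 20% mitochondrial UMIs, Cyp1a1 stood at 225 CPM and the markers at 2340 CPM. The proportion was lower there, so a relative ratio of 1 is not a firm prediction. In neutrophil-like cells the relative ratio was 0.451 (0.211 to 0.750) and in cholangiocyte-like cells 2.14 (1.72 to 2.64). Both intervals excluded 1 but crossed the limits set for the test (0.5 and 2), so the tests decided nothing. In dendritic-like cells it was 0.0640 (0.0271 to 0.109), and 0.215 (0.0887 to 0.382) without Dnase1l3 and Fcgr2b, which held 308 and 164 of the 639 marker UMIs there. No single ratio held over the 4 classes, so the match in T-like cells alone shows little. The ratio was not computed for the other classes of the PCB126 library. In its 6 plasma-like cells Cyp1a1 stood at 417 CPM (69 UMIs, with 30 of the LSEC marker Kdr). In its 11 monocyte-like cells Cyp1a1 stood at 194 CPM (49 UMIs, with 20 of Kdr). Its 55 B-like cells held 0 UMIs of Cyp1a1 and 1 of Kdr. In cholangiocyte-like cells 74.8% of the Cyp1a1 UMIs lay in the top 5 cells, so a few mixed droplets and expression in a few cells stay open.

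MHC class I genes were higher in the PCB126 library in all 5 classes compared, and MHC class II genes in cholangiocyte-like and dendritic-like cells. MHC class II medians were also above 0 in neutrophil-like cells (1.78, 4 of 5 members above 0) and vascular endothelial-like cells (2.94), but subtracting the ambient profile left 1 and 0 members of the list there. Scaling by class totals is argued against for MHC class I, since the lowest of the 5 class medians was 0.58 after centring on the median gene (0.50 to 0.68). Free RNA is argued against for MHC class II in cholangiocyte-like cells. Cd74 stood 6.94 times higher there than in neutrophil-like cells (5.13 to 9.60), the highest of 3 other classes. Against T-like cells, which were not among the 3, it was 3.63 times higher (3.01 to 4.41). Cd74 UMIs were seen in 80 of 86 cholangiocyte-like cells. At their median of 15528 UMIs free RNA alone could place a UMI in most cells, so that share decides nothing. RNA of dendritic-like cells stays open. MHC class II counts relative to 81 other dendritic-like genes were 1.96 times those in dendritic-like cells (1.82 to 2.10). That interval excluded 1, the value such RNA alone would give, but crossed the limit set at 2, so the test decided nothing. An effect of PCB126 and a difference between the mice, such as in interferon exposure, could each lie behind the pattern and were not tested.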

How the results depend on the processing

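The settings with barcodes up to 50% mitochondrial UMIs and the equally weighed clusters were chosen after seeing the data. So were the class totals without the mitochondrial genes, Gm42418, AY036118 and Lars2. The rule that a list median needs 4 members with 20 UMIs under each setting was chosen then too. No paired analysis was possible because the 2 mice share a replicate number only. For every value below the cause was not tested.

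Of 767 list medians under settings fixed in advance, 622 stayed within the counting interval of the value reported, 135 moved and 10 changed sign. Under the added settings these were 209, 48 and 3 of 260. Of 1602 gene ratios 1305 stayed, 283 moved and 14 changed sign, and under the added settings 469, 147 and 5 of 621. A change of sign was counted here only where the reported interval lay clear of 0. Other changes of sign stand among the values that stayed or moved. The immediate early median of LSEC-like cells, for instance, kept its sign in 10 of 17 alternatives. Share ratios moved in 10 of 72 cases and, under the added settings, in 8 of 19, with 1 more on the other side of 1. In all alternatives with a value the LSEC-like share ratio lay between 4.46 and 17.1 and that of neutrophil-like cells between 0.167 and 0.215. That of monocyte-like cells lay between 0.0237 and 0.0556. With each library clustered alone, 311 Control cells (16.7%) and 0 PCB126 cells were monocyte-like, so that setting gave no monocyte-like ratio. The MHC class I median lay between 0.76 and 0.98 in LSEC-like cells and between 0.72 and 0.92 in vascular endothelial-like cells.

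At Leiden resolution 0.5 the log2 ratio of Cyp1a1 was 5.20 in LSEC-like and 4.51 in vascular endothelial-like cells, that of Ltbp4 -0.42 and of Stab2 0.16 in LSEC-like cells, and the inflammatory median in LSEC-like cells -1.65. With the ambient profile subtracted the AHR battery median was 4.94 in LSEC-like and 1.96 in vascular endothelial-like cells, and the inflammatory median -0.58 in LSEC-like and 0.14 in dendritic-like cells. At most 10% mitochondrial UMIs gave an AHR battery median of 1.65, a Cyp1a1 log2 ratio of 10.64 and an inflammatory median of -0.53 in LSEC-like cells. In neutrophil-like cells it gave medians of -0.11 for heat shock and 0.32 for granule genes, and the share ratios were 6.65 for LSEC-like and 0.167 for neutrophil-like cells.

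With each library clustered alone the vascular endothelial-like share ratio was 8.63. In that class the medians were 2.66 (AHR battery), -1.96 (inflammatory), -0.38 (interferon-stimulated) and 0.18 (LSEC identity), and the log2 ratios 3.44 for Cyp1a1, 4.13 for Acta2, 2.35 for Bmp4, -0.65 for Cldn5, -0.89 for Isg15, 4.0 for Myh11, 3.11 for Myl9, 0.026 for Stab1, 4.90 for Tagln and 3.96 for Tpm2. In LSEC-like cells Cyp1a1 was at 11.44, Ltbp4 at -0.14 and the MHC class I median at 0.79. In dendritic-like cells Ccl4 was at 2.19 and the immediate early and inflammatory medians at 0.42 and 0.78.

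With cells thinned to 1000 UMIs the LSEC-like medians were 1.24 (AHR battery), 0.76 (MHC class I) and -0.51 (inflammatory), with Stab2 at 0.29. In vascular endothelial-like cells Cyp1a1 was at 4.69 and the MHC class I and antioxidant medians at 0.72 and -0.045. The granule median in neutrophil-like cells was 0.087, and 0.061 as the mean over cells. With members of at least 100 UMIs the AHR battery median was 1.94 in vascular endothelial-like cells and the inflammatory median -0.87 in LSEC-like cells. Centring on the median gene gave an MHC class I median of 0.92 in vascular endothelial-like cells. Cells with a Cyp1a1 UMI were 99.1% unthinned and 96.9% at 2000 UMIs of the PCB126 LSEC-like cells, 55.9% and 33.1% of the Control vascular endothelial-like cells, and 99.2% in both cases for PCB126.

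With clusters weighed equally, Cyp1a1 was at 6.60 in LSEC-like and 3.99 in vascular endothelial-like cells, Msr1 at 0.46, Ntn4 at 0.22, Wnt2 at -0.11 and the periportal median at 0.26 in LSEC-like cells. In neutrophil-like cells the cholesterol synthesis and interferon-stimulated medians were 0.85 and 2.40. With barcodes up to 50% mitochondrial UMIs matched to the clusters the vascular endothelial-like share ratio was 1.04. With all clustered again it was 0.928, the LSEC-like ratio 17.1 and the neutrophil-like ratio 0.169. The AHR battery median was then 1.28, the periportal median 0.24, Msr1 at 0.74 and Wnt2 at -0.060 in LSEC-like cells, and Cyp1a1 at 4.56 in vascular endothelial-like cells.

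At most 10% mitochondrial UMIs left no vascular endothelial-like class in either library, and ambient subtraction gave no value for cholangiocyte-like cells, whose hepatocyte gene CPM exceeded that of the library. Counting error limits the dendritic-like, cholangiocyte-like, neutrophil-like, vascular endothelial-like and LSEC-like comparisons, with 58, 71, 100, 127 and 143 cells in the smaller library.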

Other observations

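The unnamed cluster with C1qa and Trem2 among its top 10 genes held 44 cells of the PCB126 library and 6 of the Control library. It carried Cyp1a1 at 135.8 CPM in the PCB126 library (57 UMIs) and had 0 UMIs in the Control library. The other unnamed cluster, whose best match was LSEC, carried Cyp1a1 at 3083 CPM in the PCB126 library (333 UMIs) and had 1 UMI in the Control library. Ahrr, the AHR repressor gene, had 30 UMIs in dendritic-like cells of the PCB126 library (15.9 CPM) and 1 UMI in those of the Control library (1.35 CPM), while Cyp1a1 had 9 and 0 UMIs there.

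Hemoglobin transcripts differed between the libraries in most classes. Hbb-bs stood at 9268 CPM in dendritic-like cells of the Control library and 14.3 CPM in those of the PCB126 library, at 1284 and 35.6 CPM in vascular endothelial-like cells, and at 3287 and 3200 CPM in neutrophil-like cells. The neutrophil-like log2 ratio (-0.04) ranged from -6.79 to 12.29 over the alternatives, so its nearness to 0 depends on the setting. Opposite to most classes, B-like cells held the erythrocyte genes together at 569.4 CPM in the Control library and 6821 CPM in the PCB126 library. Barcodes with under 250 genes and at most 20% mitochondrial UMIs numbered 2262 in the Control library and 83 in the PCB126 library, and hemoglobin made up 75.1% and 81.9% of their UMIs. S100a8 and S100a9 together made up 153 CPM in LSEC-like cells of the Control library and 12.7 CPM in those of the PCB126 library.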
